A study of Mus musculus with 6 samples.

How the data were processed

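RNA of M-MDSCs sorted by flow cytometry was hybridised to 6 dual-colour Agilent mouse arrays, with mock RNA in Cy3 and RNA from azacytidine and entinostat treated mice in Cy5. Per the labels each tissue has 3 biological replicates, the mock mice were 6 to 8 weeks old, RNA was extracted with TRIzol, and about 400 ng of total RNA went into each cDNA synthesis. No array has the dyes exchanged, so dye and treatment cannot be told apart within a tissue. Each tissue lies on a slide and scan of its own, so tissue and slide cannot be told apart either.

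Per the file headers, the deposited scanner files hold intensity values per spot, raw and local background, from Agilent Feature Extraction 10.7.3.1, with probe positions on genome build mm9. The same deposited files hold processed intensity values, corrected for background and dye by the scanner software, and the log10 ratio of the processed signals. The deposited matrix of each tissue holds log2 ratios per spot and array, made by the authors with limma according to the labels. Its settings were not given in the sources used here. The matrix values equal limma's normexp correction with an offset of 50 on median signals followed by loess, as Cy5 over Cy3, with a correlation across 43173 spots of 1 and a standard deviation of the difference of 0 to 3 decimals on every array. The matrix headings name mock over treated, the opposite direction. The dyes in the labels were followed, so that a positive log2 ratio means higher in treated cells.

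The log ratios used here were computed from the mean spot signals and median local backgrounds with limma 3.58.1 in R 4.3.3 and statmod 1.5.0, by normexp background correction with an offset of 50 and loess within each array, with control spots at weight 0 and no scaling between arrays. Control spots and spots with an outlier mark of the scanner software were left out, and spots of 1 probe were averaged. The normexp fit differed between arrays: the median signal of the 153 negative control spots after correction was 240.3 in Cy5 on bone marrow replicate 1 and 87 on lung replicate 2, and from 13.32 to 15.97 on the others. Before it, the Cy5 signal of these spots minus local background was between 4.71 and 7.49 on all arrays. Their Cy3 signal minus local background was between 37.27 and 40.98 on the bone marrow arrays and between 13.79 and 16.73 on the lung arrays. After correction the Cy3 median lay between 8.35 and 52.72. The difference between arrays in the corrected Cy5 signal was the reason for an alternative with the background taken from the negative control spots. A probe was kept when the scanner software marked it as well above background on at least 2 arrays in at least 1 of the 4 combinations of tissue and channel, which left 27726 of 39429 probes. Probe names were brought to current symbols for 26581 probes by RefSeq identifier, for 2597 by symbol and for 492 by synonym, and 9759 kept their name in the file. Each gene was represented by its brightest probe, giving 22127 genes, of which 6834 carry an identifier only. Of 4593 genes with more than 1 kept probe, 6 in bone marrow and 48 in lung had probes that passed in opposite directions. Exons and UTRs behind a probe were not analysed here.

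The log2 ratios of all 6 arrays were fitted in limma with 1 mean per tissue and empirical Bayes moderation (4 residual and 3.49 prior degrees of freedom). Treated was compared with mock in bone marrow and in lung, and the response was compared between tissues as lung minus bone marrow. Mock lung was compared with mock bone marrow on the Cy3 channel after equalising the mean intensities of the arrays. Adjusted p values are Benjamini-Hochberg values of limma's two-sided moderated test over all genes tested, with a threshold of 0.05. Errors beside log2 ratios are standard deviations between the arrays of a tissue. The adjusted p rests on a spread per gene estimated over both tissues, so in bone marrow it also carries the scatter of the lung arrays, and the reverse. For 32 gene lists (pathways, cell type markers and genes tied to the drugs), camera with a preset correlation of 0.01 tested whether members ranked apart from other genes, adjusted over the lists within a comparison, and 6 genes with a missing array were left out of it. The lists, the comparisons, these tests of genes and lists and the rule for named genes were fixed before the data were examined, while the tests of explanations for the marker lists of treated lung were chosen after the results were seen. Where a mock level lay below background, the fold is a lower bound against the background level.

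By that rule the text names the 10 highest and 10 lowest log2 ratios of each comparison among genes that passed and had the same sign on all 3 arrays, or for the tissue difference those whose arrays did not overlap, with identifier-only names left out. For mock cells 5 were taken in each direction. Up to 4 members of each list with the smallest p were named, and Ccr2, Cxcr2, Adgre1, Arg1, Nos2, S100a8, S100a9 and Dnmt1 were given whatever their values. Of the genes the rule takes, 2 are not reported here. Ly6c2 was also on that last list and was not analysed here, since no tested probe carried its name. Each gene said to have risen or fallen by name did so on all 3 arrays of its tissue.

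The fit and the tests of genes and lists were tried on simulated gene-level log ratios with known changes. The noise was independent between genes, with spreads drawn from the distribution that limma fitted to the measured ratios. For mock cells the spread of the ratios was used, not that of the Cy3 signals. Background correction, loess, the filter on dim probes, probe choice and dye effects were not simulated, so these rates hold for the fit alone. Of genes changed by 1 on the log2 scale, 93% were recovered in bone marrow, 96.2% in lung and 91.3% for the difference and 87.5% for mock cells, and of genes changed by 0.5, 46%, 65.4%, 24.3% and 5.1%. Among the calls of the first 3 comparisons 3.6%, 6.8% and 6.9% were genes without a simulated change. Far fewer genes were changed in the simulation than passed in the measured data. In bone marrow 63, 71 and 66 were changed by 0.5, 1 and 2, while 14.4% of the measured genes passed. In lung 33.9% passed, for the difference 15.2% and for mock cells 65.9%. The adjusted p depends on this share, so the rates do not carry over to the measured data. Both tissues had the same simulated spread, so their rates differ by the random draw.

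The alternatives tried were processed signals, no background correction, median centring in place of loess, scaling or equalising between arrays, no filter and a strict filter on dim probes, outlier spots kept, the mean over probes, each probe on its own, a separate fit per tissue, array weights, an intensity trend, the deposited matrices, a 2-fold threshold, the replicate number as a block, the 12 channels without the array, leaving out each array in turn, and for lists an estimated correlation and the test fry. Background from the negative control spots, a tissue difference over genes detected in both tissues, and lists with processed signals were added after seeing the data.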

Results

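Gene expression was measured in monocytic myeloid-derived suppressor cells (M-MDSCs), immature myeloid cells that suppress T cells, sorted from the bone marrow or the lungs of C57BL/6 mice. Treated mice had received azacytidine, an inhibitor of DNA methyltransferases, together with entinostat, an inhibitor of class I histone deacetylases. Mock mice had received the vehicle. Each of the 6 dual-colour arrays held 1 mock RNA labelled with Cy3 and 1 treated RNA labelled with Cy5 from the same tissue, with 3 arrays for bone marrow and 3 for lung. A treated RNA was pooled from 3 to 6 mice and a mock RNA came from 1 to 2 mice. Between 49.9% and 62.8% of the spots of an array were well above background in the mock channel, and between 55.1% and 69.5% in the treated channel. The median raw signal lay between 71.6 and 100.9 intensity units in the mock channel and between 107.1 and 151.8 in the treated channel. No spot was saturated. The number of arrays limits the precision of every value.

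The first comparison asked how M-MDSCs of the bone marrow differed between treated and mock mice. Ly6a, which encodes a surface antigen of blood stem and progenitor cells, was 4.29-fold higher in treated marrow, a log2 ratio of 2.10 ± 0.16 (SD, n = 3, adjusted p = 0.000756, probe A_51_P265495 on chromosome 15 from 74825553 to 74825612 of mm9). Cd34, another progenitor antigen, rose by 1.66 ± 0.32, and Axl, a receptor tyrosine kinase that helps phagocytes clear dying cells, rose by 1.71 ± 0.37. Atf3, a stress-induced transcription factor, fell by 1.93 ± 0.52 (SD, n = 3, adjusted p = 0.00157), and Cx3cr1, the fractalkine receptor of monocytes, fell by 1.71 ± 0.97 (SD, n = 3, adjusted p = 0.0166). Signed values are log2 of treated over mock, as the dyes in the labels give it. The headings of the deposited matrices name mock over treated, a conflict in direction, while their values equal Cy5 over Cy3.

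The other genes with the highest ratios in treated marrow were Thbs1 at 1.90 ± 1.02, Ly6d at 1.85 ± 0.80, Ifitm1 at 1.81 ± 0.39, Armcx2 at 1.72 ± 0.15, Egfl7 at 1.65 ± 0.41, Angptl4 at 1.61 ± 0.33 and Selenom at 1.59 ± 0.23 (log2, SD, n = 3, adjusted p from 0.000756 to 0.0168). Thbs1 encodes the adhesive glycoprotein thrombospondin, Ly6d a surface antigen of lymphoid cells, and Ifitm1 an interferon-induced membrane protein. The other genes with the lowest ratios were Rtp4 at -1.63 ± 0.17, Prr5l at -1.56 ± 0.44 and Tef at -1.41 ± 0.24 (log2, SD, n = 3, adjusted p from 0.00149 to 0.00198). Others were Selenop at -1.36 ± 0.15, Camk1d at -1.36 ± 0.37, Ptpro at -1.36 ± 0.24 and Ifi207 at -1.33 ± 0.43 (adjusted p from 0.00149 to 0.0041). The calls for Thbs1 and Ly6d ended without bone marrow replicate 2 (adjusted p = 0.0531 and 0.0754) and without replicate 3 (adjusted p = 0.053 and 0.071). With the scanner software's processed signals the ratio was 3.30 for Ly6d, 3.36 for Armcx2 and -2.39 for Prr5l.

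Genes of the type I interferon response, an antiviral programme, were lower as a group in treated marrow. Of 28 measured members, 14 fell, 1 rose and 13 did not pass, and adjusted over the list alone 17 fell and 1 rose. Their median log2 ratio was -0.46 (camera adjusted p = 3.19e-08, and adjusted p = 0.99 with an estimated correlation). Oasl2 and Oas2, of the antiviral oligoadenylate synthetase family, fell by 1.15 ± 0.19 and by 1.05 ± 0.14, and Irf9, a transcription factor of the interferon response, fell by 0.79 ± 0.11 (log2, SD, n = 3, adjusted p from 0.00157 to 0.00236).

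Immediate early and stress genes, which are switched on within minutes of stimulation, were also lower as a group in treated marrow. Of 18 measured members, 8 fell and 10 did not pass, and adjusted over the list alone 9 fell. Their median log2 ratio was -0.42 (camera adjusted p = 4.99e-05, and adjusted p = 0.99 with an estimated correlation). Besides Atf3, Fosb, which encodes a subunit of the AP-1 transcription factor family, fell by 0.92 ± 0.54 (SD, n = 3, adjusted p = 0.0181). Its call ended without bone marrow replicate 1 (adjusted p = 0.072) or 2 (adjusted p = 0.111) and with scaling between arrays (adjusted p = 0.0754), while processed signals gave Fosb a log2 ratio of -1.57. With median centring in place of loess the list's median was 0.03 (adjusted p = 0.0742), while the interferon list kept its call at a median of -0.06 (adjusted p = 0.0269). The other 30 lists did not pass in marrow (camera adjusted p from 0.0756 to 0.975).

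Among the genes chosen in advance, Ccr2, the chemokine receptor that guides monocytes out of the marrow, fell by 0.84 ± 0.28 in treated marrow (SD, n = 3, adjusted p = 0.0198). Its call ended without any one of the bone marrow replicates (adjusted p = 0.0864, 0.0522 and 0.0886 without replicates 1, 2 and 3), with scaling between arrays (adjusted p = 0.0545) and with median centring (adjusted p = 0.609). The log2 ratio was 0.41 ± 0.24 for Cxcr2, the receptor that guides neutrophils, 0.14 ± 0.40 for the macrophage antigen gene Adgre1, 0.01 ± 0.10 for Nos2, which makes nitric oxide, and -0.01 ± 0.13 for Dnmt1, the maintenance DNA methyltransferase (SD, n = 3, adjusted p from 0.332 to 0.987). It was 0.49 ± 0.17 for S100a8 and 0.40 ± 0.07 for S100a9, which encode calprotectin (SD, n = 3, adjusted p = 0.461 and 0.598). The spread behind these p values also holds the lung arrays, with an SD of 1.39 for S100a8 and 1.57 for S100a9. With a separate fit of the marrow arrays the adjusted p was 0.046 for Cxcr2, 0.0181 for S100a8 and 0.0176 for S100a9. For Cxcr2 it was 0.0413 without lung replicate 3, and processed signals gave Cxcr2 a log2 ratio of 0.83 in marrow. Arg1, which breaks down arginine in suppressor cells, was not well above background in marrow in either channel.

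**Figure D1:**
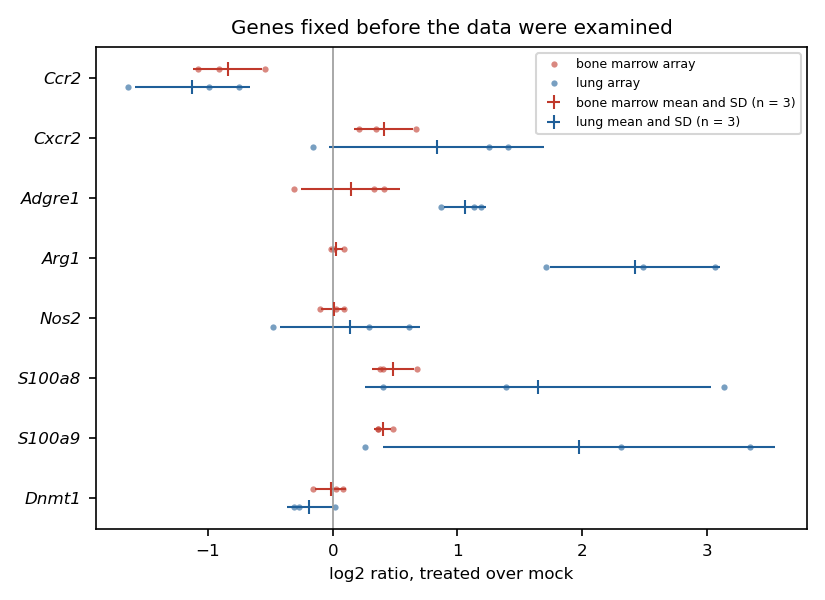
Log2 ratio of treated over mock (x axis) for the 8 measured genes chosen before the data were examined, with each array as a dot and the mean and SD (n = 3) per tissue. Ccr2 lay below 0 on every array, and Arg1, which was below background in bone marrow, was higher in treated lung at 2.42 ± 0.68.

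Over all 22127 genes tested, 3177 passed in bone marrow, 1601 higher and 1576 lower. Of these, 119 changed more than 2-fold, 93 higher and 26 lower. The median size of the log2 change among the called genes was 0.41. The count was 6504 with processed signals, of which 2794 changed more than 2-fold, 1575 higher and 1219 lower, and 5495 with background from the negative control spots, an alternative chosen after seeing the data. With median centring no gene passed in bone marrow by limma (3955 at an unadjusted p under 0.05, and Ly6a at 2.67 with adjusted p = 0.191). The median of all genes moved from 0.024 to 0.2. Leaving out 1 array at a time gave 1566, 980 and 1193 genes without bone marrow replicates 1, 2 and 3 and 1908 without lung replicate 2.

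**Figure D2:**
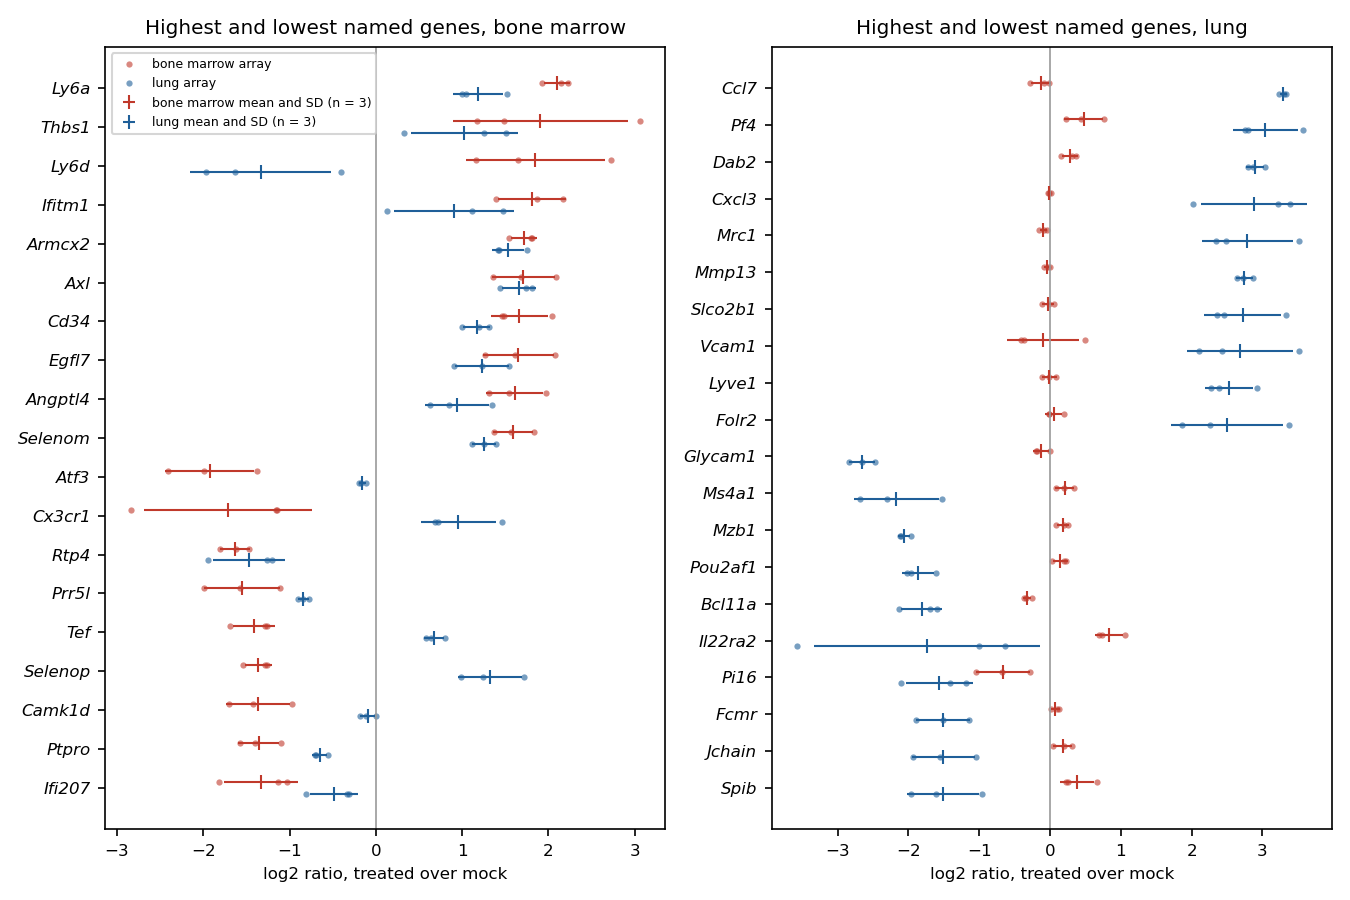
Log2 ratio of treated over mock (x axis) for the named genes with the highest and lowest ratios in bone marrow (left panel) and in lung (right panel), with every array as a dot and the mean and SD (n = 3) in both tissues. Ly6a reached 2.10 ± 0.16 in bone marrow and Ccl7 3.30 ± 0.05 in lung, and none of the genes named for marrow passed in marrow with median centring.

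The second comparison asked the same of M-MDSCs from the lung. Ccl7, a chemokine that attracts monocytes, was 9.82-fold higher in treated lung, a log2 ratio of 3.30 ± 0.05 (SD, n = 3, adjusted p = 3.23e-06, probe A_51_P436652 on chromosome 11 from 81860656 to 81860715 of mm9). Dab2, an endocytic adaptor, rose by 2.90 ± 0.13, and Mrc1, the macrophage mannose receptor, rose by 2.78 ± 0.64 (SD, n = 3, adjusted p = 4.49e-06 and 0.000133). The B-cell gene Ms4a1, which encodes CD20, fell by 2.17 ± 0.60 and the plasma-cell gene Mzb1 fell by 2.07 ± 0.09 (SD, n = 3, adjusted p = 0.000268 and 7.26e-06). Glycam1, a mucin of high endothelial venules, had the lowest ratio at -2.66 ± 0.18 (SD, n = 3, adjusted p = 7.26e-06, probe A_52_P602847 on chromosome 15 from 103393339 to 103393398).

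The other genes with the highest ratios in treated lung were the platelet chemokine gene Pf4 at 3.04 ± 0.46, the neutrophil chemokine gene Cxcl3 at 2.88 ± 0.75, Mmp13 at 2.74 ± 0.11 and Slco2b1 at 2.72 ± 0.54 (log2, SD, n = 3, adjusted p from 3.68e-06 to 0.000199). They were followed by the adhesion molecule gene Vcam1 at 2.68 ± 0.74, Lyve1 at 2.53 ± 0.35 and Folr2 at 2.50 ± 0.79 (adjusted p from 3.82e-05 to 0.000486). The other genes with the lowest ratios were Pou2af1, a B-cell coactivator gene, at -1.86 ± 0.22, Bcl11a at -1.81 ± 0.29, and Pi16 at -1.57 ± 0.48 (log2, SD, n = 3, adjusted p from 4e-05 to 0.00096). They were followed by Fcmr, the receptor for IgM, at -1.52 ± 0.38, Jchain, the joining chain of secreted antibodies, at -1.51 ± 0.44 and Spib at -1.51 ± 0.51 (adjusted p from 0.000236 to 0.000837). Il22ra2 had a ratio of -1.74 ± 1.60 (SD, n = 3, adjusted p = 0.0279), with -3.57 on 1 array. Its call ended with median centring (adjusted p = 0.187), with a separate fit (adjusted p = 0.1) and without bone marrow replicate 1 or 2 (adjusted p = 0.0542 and 0.0543). Processed signals gave 3.47 for Cxcl3, -4.88 for Glycam1, -2.43 for Il22ra2, -2.37 for Fcmr and -2.10 for Spib.

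Macrophage markers rose together in treated lung. Of 20 measured, 18 rose and 2 did not pass, also when adjusted over the list alone. Their median log2 ratio was 1.19 (camera adjusted p = 4.77e-10, and adjusted p = 0.54 with an estimated correlation). Mertk, a receptor for the uptake of dying cells, rose by 2.28 ± 0.22, the complement gene C1qc by 2.25 ± 0.47, Ms4a7 by 2.10 ± 0.27 and the transcription factor gene Maf by 1.36 ± 0.12 (SD, n = 3, adjusted p from 1.46e-05 to 0.000125). Of 17 alveolar macrophage markers, 16 rose, also when adjusted over the list alone. Their median was 1.33 (camera adjusted p = 8.98e-08, and adjusted p = 0.54 with an estimated correlation). Among them osteopontin, Spp1, rose by 1.85 ± 0.25, Plet1 by 2.04 ± 0.55 and Krt79 by 2.06 ± 0.66 (SD, n = 3, adjusted p from 4.99e-05 to 0.000446). Lysosome and phagocytosis genes moved with them: of 21, 12 rose and 1 fell, and 14 rose and 1 fell adjusted over the list alone. The median was 0.43 (camera adjusted p = 0.000331, and adjusted p = 0.54 with an estimated correlation). Among these Gas6, the ligand of Axl, rose by 2.42 ± 0.70 and the scavenger receptor gene Cd36 by 1.47 ± 0.18.

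Markers of cell types outside the sorted population moved beside these groups. Of 15 lung epithelial markers 9 rose and 6 did not pass, and 10 rose adjusted over the list alone. The median was 0.91 (camera adjusted p = 0.000299, and adjusted p = 0.54 with an estimated correlation), and processed signals gave a larger one. The surfactant genes Sftpa1, Sftpd and Sftpc rose by 2.32 ± 0.62, 2.26 ± 0.66 and 2.07 ± 0.74 (SD, n = 3, adjusted p from 0.000242 to 0.000688). Of 12 endothelial markers 11 rose, and adjusted over the list alone 11 rose and 1 fell. The median was 0.93 (camera adjusted p = 1.72e-06, and adjusted p = 0.54 with an estimated correlation). The tight junction gene Cldn5 rose by 1.51 ± 0.18 and Ramp2 by 1.58 ± 0.24. Of 12 B cell markers 9 fell and 2 rose, also when adjusted over the list alone. The median was -1.06 (camera adjusted p = 0.000299, and adjusted p = 0.54 with an estimated correlation). Cd79a, a chain of the B-cell receptor complex, fell by 1.33 ± 0.29, while the adaptor gene Blnk, which macrophages also use, rose by 1.78 ± 0.27. Of 12 NK cell markers 5 fell and 7 did not pass, and adjusted over the list alone 6 fell and 1 rose. The median was -0.21 (camera adjusted p = 0.00836, and adjusted p = 0.54 with an estimated correlation), and processed signals put it further below 0. The granzyme gene Gzma fell by 1.32 ± 0.40 (SD, n = 3, adjusted p = 0.00111), a call that ended with median centring.

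Markers of mature neutrophils rose in treated lung: 12 of 19 passed and were higher, 14 adjusted over the list alone. The median was 1.12 (camera adjusted p = 0.00138, and adjusted p = 0.59 with an estimated correlation). Some members differed widely between the lung arrays, with an SD of 1.865 for Camp, 1.51 for Ngp and 1.27 for Ltf. Of these only Ngp passed. Chil1 rose by 1.51 ± 0.22, Wfdc21 by 1.68 ± 0.31 and the gelatinase gene Mmp9 by 1.76 ± 0.60 (SD, n = 3, adjusted p from 8.73e-05 to 0.00133). For Mmp9 processed signals gave 3.103. Of 24 inflammatory cytokines and NF-kB targets, 12 rose and 1 fell, also when adjusted over the list alone. The median was 0.76 (camera adjusted p = 0.00236, and adjusted p = 0.54 with an estimated correlation). The monocyte chemokine genes Ccl12 and Ccl2 rose by 2.44 ± 0.23 and 2.17 ± 0.44, and the cytokine gene Il1a by 1.42 ± 0.19 (SD, n = 3, adjusted p from 1.46e-05 to 0.000357), with 2.45 for Il1a from processed signals. Of 12 genes of MHC class II presentation, 8 rose and 4 did not pass, and 10 rose adjusted over the list alone. The median was 0.75 (camera adjusted p = 0.000299, and adjusted p = 0.54 with an estimated correlation). H2-Eb1 rose by 2.00 ± 0.28 and the invariant chain gene Cd74 by 1.63 ± 0.37.

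Type I interferon genes were lower in treated lung, as in marrow. Of 28, 22 fell and 6 did not pass, and 25 fell adjusted over the list alone. The median was -0.77 (camera adjusted p = 2.28e-12, and adjusted p = 0.54 with an estimated correlation). Rtp4 fell by 1.47 ± 0.42, the nucleic acid sensor gene Zbp1 by 1.34 ± 0.47 and Xaf1 by 1.18 ± 0.29 (SD, n = 3, adjusted p from 0.000293 to 0.000737), and each of these calls ended with median centring. Further lists had smaller shifts. Of 19 premetastatic niche factors, genes tied to the preparation of organs for metastasis, 8 rose, 9 adjusted over the list alone. Of the 8, 5 are also on other lists, such as those of neutrophil and inflammatory genes, so that this shift is not separate from theirs. The median of the 19 was 0.39 (camera adjusted p = 0.0207, and adjusted p = 0.54 with an estimated correlation). Of 11 imprinted genes 4 rose and 1 fell, 5 and 1 adjusted over the list alone. Their median was 0.14 (camera adjusted p = 0.0258, and adjusted p = 0.54 with an estimated correlation), and the call ended without lung replicate 3 (0.0809) and with median centring (0.0692). Processed signals gave the imprinted genes a larger median, also above 0. Of 18 glycolysis genes 8 rose and 1 fell, 10 and 1 adjusted over the list alone. The median of glycolysis was 0.23 (camera adjusted p = 0.0355, and adjusted p = 0.54 with an estimated correlation), and the call ended without lung replicate 2 (0.0507) or 3 (0.104). The epsilon-sarcoglycan gene Sgce, which is imprinted, rose by 1.19 ± 0.20, and the glucose transporter gene Slc2a3 rose by 0.89 ± 0.15. The other 18 lists did not pass in lung (camera adjusted p from 0.124 to 0.89).

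**Figure D3:**
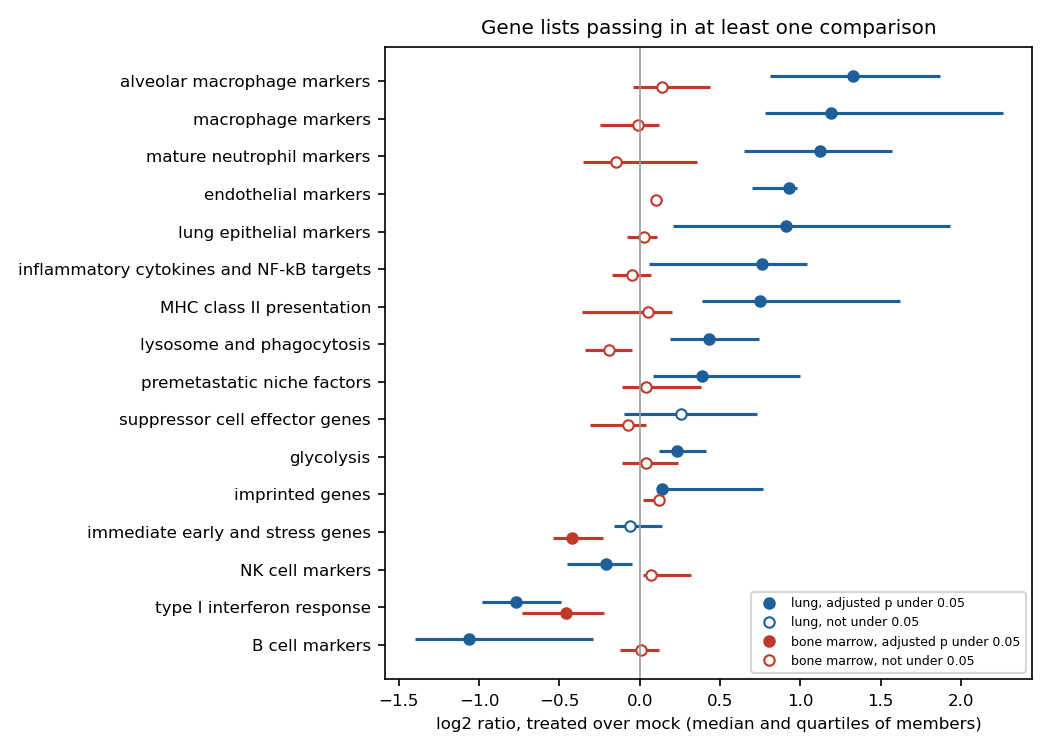
Median log2 ratio (x axis) and quartiles of the members of each fixed list that passed in at least 1 comparison, with filled marks for a camera adjusted p under 0.05 and open marks otherwise. The interferon list lay below 0 in both tissues, at -0.46 in bone marrow and -0.77 in lung, and the macrophage list reached 1.19 in lung; median centring moved the immediate early list of bone marrow to 0.03.

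Of the genes chosen in advance, Arg1 rose by 2.42 ± 0.68 in treated lung (SD, n = 3, adjusted p = 0.000268) and Adgre1 by 1.06 ± 0.17 (SD, n = 3, adjusted p = 0.0013). Ccr2 fell by 1.12 ± 0.46 (SD, n = 3, adjusted p = 0.00228, and adjusted p = 0.25 with median centring). S100a8 rose by 1.64 ± 1.39 and S100a9 by 1.98 ± 1.57 (SD, n = 3, adjusted p = 0.0202 and 0.0157), with arrays from 0.40 to 3.14 and from 0.26 to 3.35. The S100a9 call ended without lung replicate 1 (adjusted p = 0.0612) or 2 (adjusted p = 0.0665). The calls of both genes ended with median centring (S100a8 adjusted p = 0.0848, S100a9 adjusted p = 0.0625), scaling between arrays (0.0685 and 0.0534) and a separate fit (0.0825 and 0.0723). Cxcr2 had a ratio of 0.83 ± 0.87 (SD, n = 3, adjusted p = 0.0502), and without lung replicate 3 it passed at 1.33 (adjusted p = 0.000775). Processed signals gave 1.36 for Cxcr2. The ratio was 0.14 ± 0.56 for Nos2 (SD, n = 3, adjusted p = 0.601, and 0.0153 without lung replicate 1 at 0.45) and -0.19 ± 0.18 for Dnmt1 (SD, n = 3, adjusted p = 0.127).

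In lung 7503 genes passed, 4404 higher and 3099 lower, and 731 changed more than 2-fold, 570 higher and 161 lower. With processed signals 2362 of the called genes changed more than 2-fold, 1954 higher and 408 lower. The share of called genes that were higher was 58.7%, against 72.8% with processed signals and 92.4% with median centring. In the direction of the matrix headings these would be shares of lower genes, and 41.3% of the called genes would be higher. Median centring left 964 genes, 891 higher and 73 lower, of which 962 were among the 7503, and moved the median of all genes from 0.014 to 0.122, while processed signals moved it to 0.124.

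The third comparison asked where the response differed between the tissues. Each tissue had its own slide and scan, so tissue and slide cannot be told apart. A dye effect equal on both slides cancels in this difference, but one that differs between the slides does not. The Cy3 signal of negative control spots minus local background did differ. It lay between 37.27 and 40.98 on the marrow arrays and between 13.79 and 16.73 on the lung arrays. The response of Ccl7 was higher in lung than in marrow by 3.43 on the log2 scale (SE 0.10, n = 3 per tissue, adjusted p = 3.2e-05), that of Mrc1 by 2.88 (SE 0.28, adjusted p = 0.00162) and that of the lipid carrier gene Apoe by 3.04 (SE 0.40, adjusted p = 0.00445). Selenop, which encodes a selenium carrier, fell in treated marrow and rose by 1.32 ± 0.37 in treated lung, a difference of 2.68 (SE 0.19, adjusted p = 0.00057). Ly6d had the lowest difference at -3.19 (SE 0.49, adjusted p = 0.00712), and the plasma-cell gene Mzb1 had -2.25 (SE 0.09, adjusted p = 7.1e-05). Csf1r, the receptor for macrophage colony-stimulating factor, fell by 1.14 ± 0.29 in treated marrow and rose by 0.76 ± 0.23 in treated lung, a difference of 1.90 (SE 0.17, adjusted p = 0.00133). With processed signals the difference of Mzb1 was -3.93. In marrow Ccl7 was well above background on 2 arrays in the mock channel and 1 in the treated channel, and Mzb1 on 1 and 3. With median centring the calls for Ccl7, Mrc1 and Mzb1 remained and those for Apoe, Selenop, Ly6d and Csf1r ended.

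**Figure D4:**
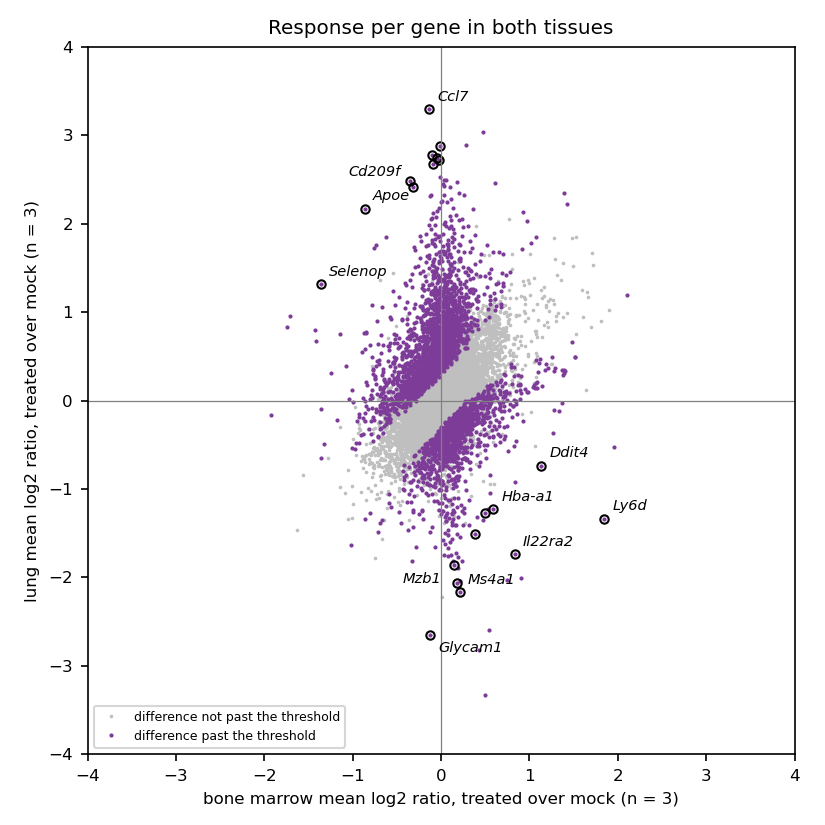
Mean log2 ratio of treated over mock in bone marrow (x axis) and in lung (y axis) for each gene tested, with genes whose tissue difference passed in purple and named genes labelled. Ccl7 stands apart in lung at 3.30 ± 0.05, and Selenop lay at -1.36 ± 0.15 in bone marrow and 1.32 ± 0.37 in lung.

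Macrophage markers responded more strongly in lung: 17 of 20 had a higher response there, also when adjusted over the list alone. The median difference was 1.42 (camera adjusted p = 1.26e-12, and adjusted p = 0.57 with an estimated correlation). Above background in marrow were 17 of the 20, and 15 of these had a higher response. Beside them stood 11 of 17 alveolar macrophage, 7 of 15 lung epithelial and 9 of 12 endothelial markers with a higher response in lung (12, 10 and 9 adjusted over the list alone, with 1 lower endothelial marker). The median differences were 1.16, 0.62 and 0.81 (camera adjusted p = 1.12e-05, 0.000137 and 4.93e-06, and adjusted p = 0.57 with an estimated correlation for each). Above background in marrow were 15 of the 17 alveolar macrophage, 4 of the 15 lung epithelial and 4 of the 12 endothelial markers, and 10, 1 and 2 of these had a higher response in lung. For the others the marrow ratio carried no signal, and the difference restates the lung value. With processed signals the endothelial list had an adjusted p of 0.228, and the differences of the epithelial gene Cdh1 and of Cldn5 were -0.84 and -0.32. In marrow Cdh1 was above background in both channels, and Cldn5 only in the treated channel, on 2 arrays. Of 12 B cell markers 7 had a lower and 2 a higher response in lung, 8 and 2 adjusted over the list alone. The median difference was -0.92 (camera adjusted p = 0.000256, and adjusted p = 0.57 with an estimated correlation). Of the 7 above background in marrow, 4 had a lower and 2 a higher response.

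Genes of MHC class II presentation had a higher response in lung for 8 of 12 members, also when adjusted over the list alone. The median difference was 0.83 (camera adjusted p = 0.000137, and adjusted p = 0.57 with an estimated correlation). H2-Eb1 differed by 1.97 (SE 0.22) and H2-Aa by 2.19 (SE 0.32), calls that ended with median centring. Inflammatory cytokines and NF-kB targets were higher for 8 of 24, 10 adjusted over the list alone, at 0.62, and lysosome and phagocytosis genes for 10 of 21, 16 adjusted over the list alone, at 0.55 (camera adjusted p = 1.89e-05 and 4.93e-06, and adjusted p = 0.57 with an estimated correlation for both). Of the inflammatory genes 18 were above background in marrow, and 5 of these had a higher response, while all 21 lysosome genes were above it. For mature neutrophil markers 6 of 19 were higher, 7 and 1 lower adjusted over the list alone, at 1.42 (camera adjusted p = 0.000682, and adjusted p = 0.59 with an estimated correlation). For immediate early and stress genes 5 of 18 were higher, 6 adjusted over the list alone, at 0.44 (camera adjusted p = 0.00187, and adjusted p = 0.59 with an estimated correlation). For suppressor cell effector genes 4 of 22 were higher, 5 adjusted over the list alone, at 0.45 (camera adjusted p = 0.00241, and adjusted p = 0.57 with an estimated correlation), and 3 were higher among the 20 above background in marrow.

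The remaining lists with a tissue difference shifted less. For NK cell markers 3 of 12 were lower, 6 adjusted over the list alone, at -0.28 (camera adjusted p = 0.000438, and adjusted p = 0.57 with an estimated correlation), and all 3 were among the 8 above background in marrow. For type I interferon genes 3 of 28 were lower and 1 higher, 5 and 1 adjusted over the list alone, at -0.27 (camera adjusted p = 0.00702, and adjusted p = 0.75 with an estimated correlation). The call of the type I interferon response ended without bone marrow replicate 1 (0.195), without lung replicate 1 (0.0517) and with processed signals (0.12). For premetastatic niche factors 4 of 19 were higher, also when adjusted over the list alone, at 0.18 (camera adjusted p = 0.0365, and adjusted p = 0.57 with an estimated correlation), and 3 were higher among the 14 above background in marrow. The call of the niche factors ended without bone marrow replicate 1 (0.0594) or 3 (0.0759), without lung replicate 2 (0.0815) or 3 (0.0626), with processed signals (0.276) and with background from the negative control spots (0.0571).

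The difference passed for 3365 genes, 2163 higher and 1202 lower in lung, and 617 differed more than 2-fold. Processed signals gave 2850 called genes past 2-fold, 1996 higher and 854 lower in lung. Of the 3365, 2767 were well above background in both tissues, 582 were not in marrow and 16 were not in lung. The share with a higher response in lung was 64.3%, and 84.8% with median centring, which left 33 genes, 28 higher and 5 lower (2155 at an unadjusted p under 0.05). In the direction of the matrix headings 35.7% would have the higher value in lung. Without bone marrow replicates 1, 2 and 3 the count was 1974, 1480 and 2206.

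The calls of both tissues also overlapped. Treated RNA carried Cy5 on all arrays, so independent calls are not the level to be met without a response, and a dye effect shared by the tissues is contained in each of these values. Across genes the mean log2 ratios of marrow and lung correlated with r = 0.31 and rho = 0.32, and genes are not independent replicates. Both tissues called 757 genes higher, where 319 would meet if the calls were independent, and 656 genes lower, where 221 would meet. Axl, Armcx2 and Selenom rose in both, with Axl at 1.71 ± 0.37 in marrow and 1.66 ± 0.20 in lung, and Rtp4 fell in both. Opposite calls were made for 128 genes lower in marrow and higher in lung (314 if independent) and 67 genes higher in marrow and lower in lung (224 if independent). The chemokine gene Ccl5 was among the latter at 0.83 ± 0.35 and -0.92 ± 0.09, with 1.38 in marrow from processed signals.

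The mock channels, which carried 1 dye on all arrays, gave the difference without the drugs between cells sorted as M-MDSCs from lung and from marrow. The surfactant gene Sftpc was at least 99.7-fold higher in mock lung (adjusted p = 2.11e-07), since marrow lay below background, and the scavenger receptor gene Marco was 58-fold higher (log2 5.86, SE 0.09, n = 3 per tissue, adjusted p = 3.12e-08). Hspb1, Tgm2 and Ctsk followed at least 66.2-fold, 53.8-fold and at least 50.4-fold higher. The neutrophil granule genes Mpo, Ctsg and Camp had log2 differences of -7.86 (SE 0.57), -7.02 (SE 0.24) and -6.24 (SE 0.64), and Ms4a3 and Tns1 had -6.55 (SE 0.23) and -6.37 (SE 0.11), with adjusted p from 3.12e-08 to 7.58e-05. Of 27 proliferation genes 26 were lower in mock lung, with a median of -2.23, and of 20 macrophage markers 16 were higher, with a median of 1.85. Among markers of other cell types, 12 of 15 lung epithelial, 12 of 12 fibroblast and stromal and 11 of 12 B cell markers were higher. The difference can therefore not be assigned to M-MDSCs alone. In contrast, 13 of 19 mature neutrophil markers were lower and 1 higher (median -1.44), and 5 of 13 erythroid markers were lower and 1 higher (median -0.58). No test of whole lists was run for mock cells. In all 14580 genes differed, 6544 higher and 8036 lower in lung, and here too tissue and slide cannot be told apart.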

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

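The tests on marker lists of treated lung were chosen only after the results were seen, while the tests on second probes and on splits of the arrays were set beforehand. The response to treatment differed between lung and bone marrow for 3365 genes by limma's test of the difference itself, which is what drew attention to the values that follow. All are log2 values of lung minus bone marrow with 3 arrays per tissue, and tissue and slide cannot be told apart.

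Among the gene lists, the median difference was 1.42 for macrophage markers, 1.42 for mature neutrophil markers, 1.16 for alveolar macrophage markers, 0.83 for MHC class II presentation and 0.81 for endothelial markers. It was 0.62 for inflammatory cytokines and NF-kB targets, 0.62 for lung epithelial markers, 0.55 for lysosome and phagocytosis genes, 0.45 for suppressor cell effector genes, 0.44 for immediate early and stress genes and 0.18 for premetastatic niche factors. Only 4 of 12 endothelial and 4 of 15 lung epithelial markers were above background in bone marrow, so that these differences largely restate the lung values. The median was -0.92 for B cell markers, -0.28 for NK cell markers and -0.27 for the type I interferon response.

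Among the genes, the highest differences were 3.43 for Ccl7, 3.04 for Apoe, 2.88 for Cxcl3, 2.88 for Mrc1, 2.83 for Cd209f, 2.79 for Mmp13, 2.78 for Vcam1, 2.75 for Slco2b1, 2.73 for Gas6 and 2.68 for Selenop. Of these, Cxcl3, Mmp13 and Slco2b1 were not well above background in bone marrow in either channel. Ccl7 was above it on 2 marrow arrays in the mock channel and 1 in the treated channel, Cd209f on 2 and 0, and Gas6 on 3 and 1. The marrow values of these genes therefore lay near background. The call for Cd209f ended without bone marrow replicate 2 (adjusted p = 0.05). The lowest differences were -3.19 for Ly6d, -2.57 for Il22ra2, -2.53 for Glycam1, -2.38 for Ms4a1, -2.25 for Mzb1, -2.01 for Pou2af1, -1.89 for Spib, -1.87 for Ddit4, -1.81 for Hba-a1 and -1.77 for Hba-a2. Glycam1, Ms4a1 and Pou2af1 were below background in bone marrow. With median centring the calls for Ccl7, Cxcl3, Mrc1, Mmp13, Slco2b1, Glycam1 and Mzb1 remained and the others ended. The call for Il22ra2 (adjusted p = 0.0447) ended without any one of the bone marrow arrays (adjusted p = 0.1, 0.125 and 0.113 without replicates 1, 2 and 3) and without lung replicate 2 (adjusted p = 0.0585). That for Ddit4 ended without bone marrow replicate 1 or 3 (adjusted p = 0.0593 and 0.0555). Those for Hba-a1 (adjusted p from 0.0818 to 0.119) and Hba-a2 (adjusted p from 0.092 to 0.119) ended without any 1 of the bone marrow arrays and without lung replicate 1 or 3.

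Macrophage markers were higher and B cell markers lower in treated lung. A lower share of the sorted cells, with every other cell type higher alike, would raise B cell markers too. The gap between the medians of both lists was 2.25, beyond the sum of 1.95 of their spreads. This gap restates the pattern it was chosen for, so it argues only against an equal rise of all other cell types. A lower share of the sorted cells with unequal changes of other cell types was not tested. Alveolar macrophages among the sorted cells may account for part of it: 94.1% of their measured markers, 16 of 17, passed and were higher. This share is not particular to them, since 91.7% of the endothelial markers, 11 of 12, also passed and were higher. Endothelial RNA in the treated lung samples was not tested as an explanation. Yet 15 of the 17 were also above background in marrow, where 3 rose with treatment, among them Spp1 by 1.07 ± 0.10. Marco and Spp1 reached log2 levels of 14.13 and 12.6 in treated lung. Marco was already higher in mock lung than in mock marrow, and its ratio in lung was 0.76 ± 0.80 (SD, n = 3, limma adjusted p = 0.0465). None of the 17 is on another of the fixed lists, which does not show that they are specific to alveolar macrophages. The sort for M-MDSCs would remove such cells where it was complete. Transcripts of epithelial markers were present in mock and treated lung. The surfactant genes Sftpa1, Sftpb, Sftpc and Sftpd were above background on all 3 lung arrays in both channels and on no marrow array. They rose by 2.32, 1.97, 2.07 and 2.26, with Sftpc at a log2 level of 15.17 in treated lung. How far epithelial RNA underlies the macrophage and B cell shifts stays open. Of the lung epithelial markers 60% passed and were higher, which decides neither way, and 4 of the 15 were above background in marrow. An effect of the drugs on the sorted cells themselves stays open and was not tested apart from these.

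No array has the dyes exchanged, so a dye bias of single probes could underlie calls within a tissue. For called genes with a second probe elsewhere on the gene, the median signed log2 ratio of the other probes was 0.42 of that of the tested probes in bone marrow (bootstrap interval of 95%, 0.39 to 0.46, 769 genes, 82.7% of the same sign) and 0.41 in lung (0.38 to 0.45, 1606 genes, 81% of the same sign). Both lie between the bounds set for either outcome, and genes not called in bone marrow had 0.46. The tested probe was the brightest of its gene, so the other probes were dimmer. In bone marrow the slope of these ratios on processed ratios was 0.9 among the brightest genes and 0.12 among the dimmest. Called genes were also chosen by the ratio of their tested probe. Dimmer probes and this choice can both lower the value without dye bias, so the test cannot decide. Dye and treatment also go together on each array, so dye bias and response to the drugs cannot be told apart for these genes.

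As a check on grouping, the sign of arrays was changed within a tissue, which gives 4 patterns, and the 6 arrays were split 3 against 3, which gives 10 splits. The real pattern gave 3177 genes in bone marrow and 7503 in lung, the real split 3365 for the tissue difference and 14580 for mock cells, and the highest of the others gave 0 in each. In each case 1 pattern or split, the real one, gave as many genes. These numbers of splits are too few for a share under 0.05. The other patterns and splits also move a shared difference into the spread between arrays. Few calls were to be met there, so the 0 calls lend no support.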

How the results depend on the processing

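The alternatives with background from the negative control spots, with genes detected in both tissues alone, and with processed signals for lists were chosen after seeing the data. The number of arrays and the signal over background limit all counts: between 49.9% and 69.5% of spots were well above background per channel. For bone marrow the count of 3177 genes became 6504 with processed signals, 5495 with background from the negative control spots, 0 with median centring by limma (3955 at an unadjusted p under 0.05) and 119 with a 2-fold threshold. Leaving out 1 array gave from 980 to 4066, with 1566, 980 and 1193 without bone marrow replicates 1, 2 and 3 and 1908 without lung replicate 2. For lung, 7503 became 964 with median centring and 731 with a 2-fold threshold, and 5124 to 7768 without 1 array. For the tissue difference, 3365 became 33 with median centring, 617 with a 2-fold threshold and 1480 to 2819 without 1 array. A 2-fold threshold lowers a count by construction. Leaving out a lung array keeps the bone marrow ratios, so it moves the bone marrow count through the spread estimated over both tissues. For the other settings the cause was not tested. The count for lung versus bone marrow in mock cells stayed between 12758 and 15786 under the alternatives run for it, which held no 2-fold threshold, and 3701 of the 14580 genes differed more than 2-fold. Apart from the fit without the array as a block, the other alternatives kept each count within 1.5 times.

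The replicate number was also tried as a block. The correlations of the deviations of arrays with the same number were 0, 0.12 and 0.05, and those with different numbers lay between -0.12 and 0.04. With 3 arrays per tissue these values cannot decide whether the number pairs the tissues. The labels do not say whether the same mice gave both, and the tissues were treated as unpaired. As a random block it gave 3214 genes in bone marrow and 7503 in lung, and as a fixed block 2853 for the difference and 13544 for lung versus bone marrow in mock cells. Without the array as a block, with the 12 channels as separate samples, 1786 genes passed in bone marrow and 5841 in lung.

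Of the gene lists, 2 passed in bone marrow, 14 in lung and 14 for the difference. With an estimated correlation 0 passed in each, and fry gave 0 in bone marrow, 19 in lung and 9 for the difference in 1 direction and 24, 32 and 31 in either direction. Median centring gave 7 lists in bone marrow, and leaving out 1 array gave 2 to 6 there, 13 to 17 in lung and 12 to 15 for the difference. For these the cause was not tested, except that fry compares no list with other genes.

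With median centring these bone marrow values turned from below to above 0: the immediate early list to 0.03, Cebpe 0.07, Cybb 0.19, Dnajb1 0.12, Grn 0.19, Gsr 0.33, Hdac5 0.03, Jun 0.18, Jund 0.04, Ncf1 0.04, Ncf4 0.12, Npc2 0.06, Sirt1 0.09 and Stat3 0.16. With the mean over probes Srebf2 in lung was -0.01, and with processed signals the tissue difference was -0.84 for Cdh1, -0.5 for Cdh5, -0.32 for Cldn5 and 0.75 for Vpreb3. For all of these the cause was not tested. Among calls of named genes, 333 kept their direction and lost the threshold with median centring, 86 with scaling between arrays, 64 with processed signals and 58 without the array as a block, and 39 to 104 did so without 1 array.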

Other observations

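The test of single-probe noise and that of brightness were set beforehand, and no test of this part was chosen after its result was seen. Chemokine receptors and trafficking genes went both ways. In treated marrow 5 of 20 rose and 3 fell, and in treated lung 8 rose and 6 fell (camera adjusted p = 0.703 and 0.375). The formyl peptide receptor gene Fpr1 rose in marrow by 1.29 ± 0.55, and the integrin gene Itga4 fell by 0.79 ± 0.16 (log2, SD, n = 3). In lung the complement receptor gene C5ar1 rose by 1.57 ± 0.14 and S1pr1 by 1.28 ± 0.20. Of 22 suppressor cell effector genes 4 fell in marrow, and 11 rose and 2 fell in lung (camera adjusted p = 0.176 and 0.146). Of 18 classical monocyte markers 3 rose and 5 fell in marrow, and 2 rose and 7 fell in lung (camera adjusted p = 0.213 and 0.142). Of 19 genes known to respond to histone deacetylase inhibitors, 5 rose and 1 fell in marrow, and 7 rose and 2 fell in lung (camera adjusted p = 0.483 and 0.727). Among them the metallothionein gene Mt2 rose by 1.16 ± 0.28 in marrow and Txnip by 1.64 ± 0.25 in lung. Of 22 DNA methylation and histone deacetylase enzymes, 2 rose and 2 fell in marrow, and 4 rose and 3 fell in lung (camera adjusted p = 0.975 and 0.836). Hdac7 rose by 0.53 ± 0.06 in marrow, and Hdac9 rose by 1.13 ± 0.37 in lung.

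Of 9 measured germline genes silenced by methylation, 2 rose in each tissue (camera adjusted p = 0.821 and 0.575). Of 18 p53 targets and DNA damage genes 3 rose in marrow, and 6 rose and 2 fell in lung, where Sesn1 rose by 1.18 ± 0.13 (camera adjusted p = 0.35 and 0.255). Of 18 cholesterol synthesis genes 3 rose and 1 fell in marrow, and 5 rose and 3 fell in lung, where Insig1 fell by 0.84 ± 0.11 (camera adjusted p = 0.372 and 0.77). Of 27 proliferation genes 5 rose in lung (camera adjusted p = 0.975 in marrow and 0.151 in lung). Of 14 primary granule and progenitor genes 2 rose and 1 fell in marrow, and 5 rose and 1 fell in lung (camera adjusted p = 0.35 and 0.124). Of 16 MHC class I genes 2 fell in marrow, and 4 rose and 7 fell in lung (camera adjusted p = 0.718 and 0.156). Markers of dendritic cells rose for 3 and fell for 2 of 13 in lung, where Cd83 rose by 1.74 ± 0.12, and T cell markers rose for 2 and fell for 3 of 14 (camera adjusted p = 0.668 and 0.295). In lung 3 of 13 erythroid markers rose and 4 fell, and 2 rose and 2 fell of 12 fibroblast and stromal, of 9 mast cell and basophil, and of 9 megakaryocyte and platelet markers (camera adjusted p = 0.489, 0.77, 0.673 and 0.89). Among the last, the platelet chemokine gene Ppbp rose by 2.25 ± 0.19 and the integrin gene Itgb3 fell by 0.71 ± 0.09, a call that ended with median centring. The haemoglobin genes Hba-a1 and Hba-a2 had ratios of -1.23 ± 1.12 and -1.27 ± 1.09 in lung (adjusted p = 0.0277 and 0.0233), with 0.04 and -0.02 on lung replicate 2, and both calls ended without lung replicate 1 (adjusted p = 0.113 and 0.0998) or 3 (adjusted p = 0.122 and 0.106). For some lists that did not pass, the median, the mean and the test differed in sign. These were B cell, dendritic cell, erythroid, germline, MHC class I, MHC class II and proliferation genes in marrow, and enzyme, immediate early, mast cell and megakaryocyte lists in lung. For the difference they were monocyte, dendritic cell, enzyme, fibroblast, megakaryocyte, MHC class I, p53 and progenitor lists.

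With processed signals 2794 genes passed and changed more than 2-fold in bone marrow, against 119. Smaller ratios of dim probes under the offset of 50 are a candidate explanation: the slope of the ratios used here on the processed ratios was 0.9 among the brightest of 3 equal groups of genes and 0.12 among the dimmest, which held 2275 of the 2675 added genes. Of the added genes 614 also passed here at smaller changes, and 894 were not well above background in bone marrow. Noise or dye bias of single probes may contribute as well, since other probes of the added genes gave 0.24 of the processed ratio of the tested probes (bootstrap interval of 95%, 0.15 to 0.38, 63.5% of the same sign). Genes not called in bone marrow with processed signals gave 0.72 (0.66 to 0.81). The added genes were chosen by the ratio of their tested probe, which by itself lowers their value. The value of 0.24 for the added genes lies, with its interval, across the bound set for it. Noise and a response of dim genes to the drugs can therefore not be told apart.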
